A study of Arabidopsis thaliana with 4 samples.

How the data were processed

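RNA from the elongation zone of Arabidopsis thaliana inflorescence stems was compared between wild type (Col) and eal1 on 4 Agilent 2-colour arrays. Per the labels' protocols, seeds were kept cold for 3 days, grown on plates for 10 days at 23 °C under constant light and then moved to soil. A stem piece of 1.5 cm, reaching from 0.3 to 1.8 cm below the apex, was cut from primary stems of 5 to 8 cm without their lateral organs, and each preparation pooled at least 10 plants. Per the labels' protocols, 500 ng of total RNA was amplified and each RNA was labelled with Cy3 and with Cy5 in separate reactions.

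Each scanner file gives, per the file headers, spot intensity in both dye channels, extracted with Feature Extraction 9.1.3.1 and not normalized in the mean and background columns used here. The deposited value table holds a log10 ratio of Cy5 over Cy3 per spot. It equals the scanner file's own log ratio for every spot (largest difference 0), has a median of 0 in each column, and was not turned by genotype. Within the scanner files the processed intensity behind that ratio was background-subtracted and dye-normalized by the software, per the file headers. All 4 arrays lay on 1 slide and were read in 1 scan, so neither could be tested as a batch.

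The labels give 2 groups of 2 arrays, named here the eal1-1 pair and the eal1-2 pair. In replicate 1 of each pair wild type carried Cy5, and in replicate 2 eal1 did. The genotype label of both is eal1, and whether the names stand for alleles or for preparations is not given in the sources used here. Because each RNA was labelled with both dyes, the arrays of a pair were taken as a technical dye swap of 1 RNA pair and averaged. The labels also use the word biological for these replicates, and the reading of the 4 arrays as 4 replicates was run as an alternative. The replicate number marks the dye orientation, so a fit with it as a block holds a dye term.

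Background was corrected by normexp with an offset of 50, and ratios were normalized by loess within each array in limma 3.58.1 under R 4.3.3. The 1417 control spots of each array were given no weight in loess and left out afterwards. Each array had 37685 other spots for 37478 probes, of which 0 were saturated. Spots of a probe were averaged, and 172 probes flagged as outliers on any array were left out. A probe was kept if it was well above background on all 4 arrays in the channel of at least 1 genotype. The brightest probe stood for a gene. This left 18374 genes, 389 of which had more than 1 such probe, and in 3 of those the probes differed in sign beyond 0.2 on the log2 scale. The share of probe spots well above background lay between 58.8% and 61.8% in Cy3 and between 64.7% and 67.6% in Cy5. The number of arrays limits the precision.

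Gene names came from the scanner files, which name 26236 probes by 25665 loci, and 25449 of these loci matched the TAIR10.1 reference table, used for names only. The other 11242 probes carry no locus and were tested apart. The LZY names come from the gene lists.

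Log2 ratios of eal1 over wild type were tested against 0 with limma (lmFit and eBayes) over 2 RNA pairs, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) are those of this fit, with n = 2 RNA pairs. The fit draws each gene's spread toward a value common to all genes (6.5 prior degrees of freedom). The smallest SEs mostly reflect that value and not the gene's own spread. The p-values of this fit measure the spread between the 2 eal1 RNAs. A wild-type extract used in both pairs would add nothing to that spread, and whether there was 1 is not given in the sources used here. As an alternative chosen after seeing the data, the variance was multiplied by 3, as for 1 wild-type extract with the spread of eal1. Sets were tested with limma's camera at an inter-gene correlation of 0.01 over 21 gene lists with 414 members, of which 349 were measured. Camera at that preset value compares a list's genes with other genes, so its p does not measure the spread between RNA pairs. With an estimated correlation, camera has the 1 residual degree of freedom that 2 RNA pairs leave. It could then hardly call a list, so a high p in that setting decides little. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names SHR, SCR and the LZY genes, the 10 largest changes per direction among called genes with 1 sign on all 4 arrays, and up to 4 called members per list (or 2 members given as values). Where a genotype was not well above background on any array, the ratio is given as a lower bound: the brighter genotype's mean over the dimmer one's, the latter set on each array to the higher of its own signal and the lowest signal well above background, after loess and Aquantile. The difference between the pairs was tested on single arrays with the dye term in the model, which measures technical error only.

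The fit was tested on simulated data with 50 changed genes at each of 4 sizes among 18374 and the dye terms of the real arrays. Of the genes changed by 0.25, 0.5, 1 or 2 on the log2 scale, 26%, 94%, 100% and 100% were called, beside 7 unchanged genes. When the simulated pairs shared 1 wild-type extract with the spread of eal1, 868 unchanged genes were called, 82.3% of the calls. With no list changed, 0 lists were called. Genes were drawn independently in this simulation, so it cannot show how correlation between genes affects the list test. The spreads were drawn from the prior of the fit itself, so the call rates hold only under its model. The share of 82.3% also depends on the number of genes changed and does not carry over to the real calls.

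Alternatives covered the background correction, the normalization, the filter on dim probes, the probes per gene, the deposited ratios, the model of replication, the list test, each array left out and each pair left out.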

Results

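Gene expression was measured in the elongation zone of the inflorescence stem of wild type and of eal1, a shoot gravitropism mutant that carries an allele of SHORT-ROOT (SHR), the GRAS transcription factor that specifies the endodermis. Each of 2 eal1 RNAs was hybridised against wild type on a dye-swapped pair of arrays, 4 arrays in all, and 18374 genes were tested. The comparison asks which genes differ between the mutant and the wild-type stem.

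The 10 largest decreases in eal1 included TAC1 and LZY1, both of the LAZY family, and the actin-binding gene ADF9. TAC1 (AT2G46640), which widens branch angle, was at least 11.6-fold lower (limma adjusted p = 1.6e-06), since eal1 was not well above background on any array. LZY1 (AT5G14090), which acts downstream of amyloplast sedimentation in shoot gravitropism, fell by 2.38 on the log2 scale (SE 0.08, adjusted p = 8.2e-06). ADF9 (AT4G34970) fell by 2.49 (SE 0.05, adjusted p = 1.6e-06). SCR (AT3G54220), the partner and target of SHR in the endodermis, fell by 0.63 (SE 0.04, adjusted p = 1.5e-04). SHR itself (AT4G37650) had a log2 ratio of -0.11 (SE 0.05, adjusted p = 0.166), with -0.21 in the eal1-1 pair and -0.01 in the eal1-2 pair. The SHR transcript level checks nothing about the genotype, since an allele can alter the protein sequence without changing that level.

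Among the other large decreases, the acireductone dioxygenase gene ARD3 had a log2 ratio of -1.77 (SE 0.10), PRA1.F1 of -1.64 (SE 0.05) and the leaf senescence and defence regulator WRKY53 of -1.62 (SE 0.04). The pectin methylesterase gene ATPMEPCRB had a ratio of -1.48 (SE 0.04), the F-box gene SNE of -1.44 (SE 0.04), AT4G14980 of -1.26 (SE 0.10) and QQS, a regulator of starch content, of -1.23 (SE 0.05). The largest increases were those of AT5G05250 with a log2 ratio of 1.55 (SE 0.06), AT2G05540 with 1.42 (SE 0.09), AT3G01345 with 1.32 (SE 0.18), the protein kinase gene CIPK20 with 1.31 (SE 0.07) and the galactinol synthase gene GolS1 with 1.31 (SE 0.07). They were followed by AT4G36850 with 1.23 (SE 0.08), AT2G15020 with 1.05 (SE 0.05), the clock-associated genes LNK4 with 1.04 (SE 0.05) and LNK3 with 1.01 (SE 0.04), and AT3G28220 with 0.98 (SE 0.04). The limma adjusted p of these genes was at most 0.0021, the value of AT3G01345. That gene had log2 ratios of 0.84 in the eal1-1 pair and 1.79 in the eal1-2 pair, and adjusted p = 0.0628 in limma with wild type given the spread of eal1.

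On all 4 arrays, 14 genes differed at least 2-fold. The 10 lower in eal1 were TAC1, ADF9, LZY1, ARD3, PRA1.F1, WRKY53, ATPMEPCRB, SNE, QQS and the zinc finger gene SGR5. The 4 higher were AT5G05250, AT2G05540, CIPK20 and GolS1. No model of the spread enters this count, but it became 62 with the deposited ratios (18 higher, 44 lower), 38 with normexp without an offset and 6 with median centring (1 higher, 5 lower).

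Over all genes, limma called 5434 of 18374 genes, 2706 higher and 2728 lower in eal1. Most of these changes were small under the main processing. Its normexp offset is added to both channels, which by construction shrinks the ratios of dim genes. The sizes below therefore hold for that setting. The median absolute log2 ratio of called genes was 0.21, 5120 were under 0.5, and 32 reached 1, 9 of them higher and 23 lower. All 4 arrays had the same sign for 4479 called genes (82.4%), and for 37.4% of all tested genes. With wild type given the spread of eal1, limma called 770 genes, 348 higher and 422 lower. With median centring in place of loess the count was 953, 328 higher and 625 lower, and without eal1-2 replicate 2 it was 2065. Without eal1-1 replicate 1 the count was 2882.

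**Figure D1:**
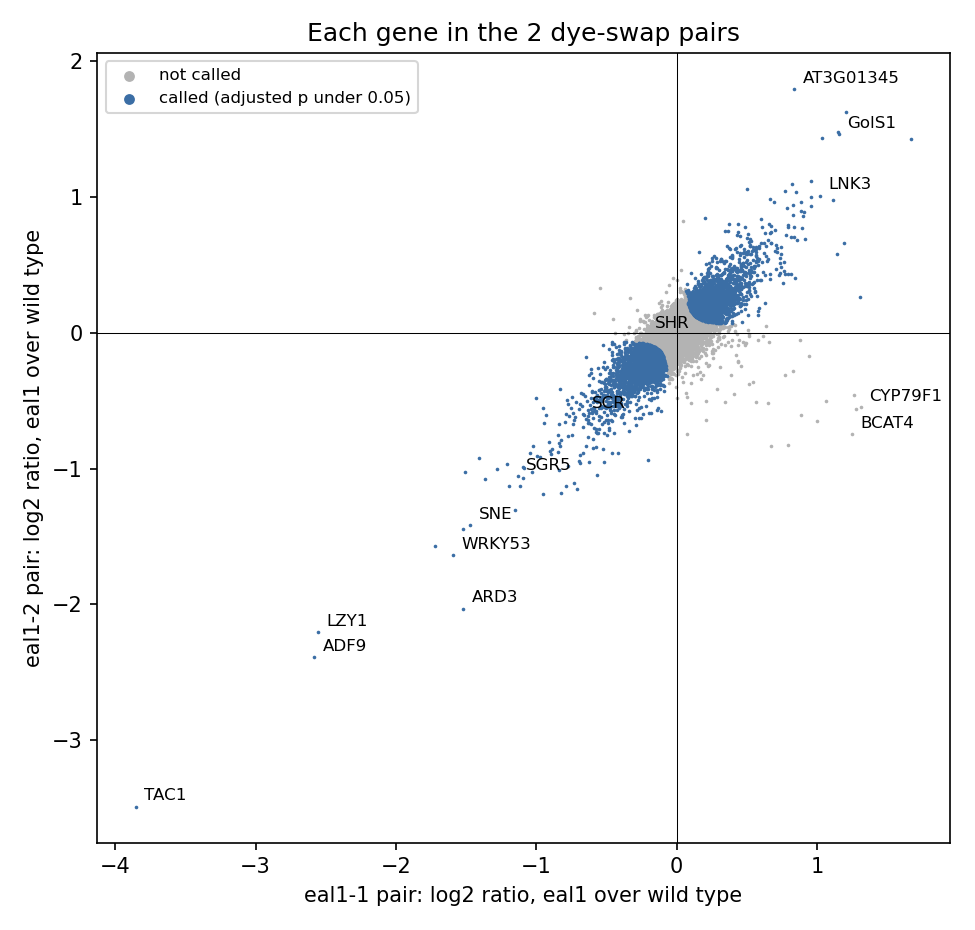
Log2 ratio of eal1 over wild type for each of 18374 genes in the eal1-1 pair (horizontal axis) and in the eal1-2 pair (vertical axis), each the mean of 2 dye-swapped arrays, with called genes in blue and the others in grey. TAC1, ADF9 and LZY1 lie farthest below 0 in both pairs, TAC1 being drawn at its fitted ratio although eal1 was not well above background, while CYP79F1 and BCAT4 lie above 0 in the eal1-1 pair and below 0 in the eal1-2 pair.

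The SHR pathway list was lower in eal1, with a median log2 ratio of -0.12 and a mean of -0.27. Of 14 measured members, 7 fell, 2 rose and 5 did not pass the test, and the numbers were the same when adjusted over the list alone. The log2 ratio was -1.44 for SNE, -1.09 for SGR5, a regulator of early gravitropic events, -0.63 for SCR and -0.55 for SCL23, a GRAS gene close to SCR. NUC and IDD16 rose by 0.38 and 0.17, and SHR, MGP, JKD, RLK (AT5G67280) and IDD14 did not pass. The list shifted downward by limma's camera (adjusted p = 0.0278), while adjusted p = 0.928 with an estimated correlation, a setting that could hardly call any list. The call was also lost with normexp without an offset (adjusted p = 0.0501), with the deposited ratios (adjusted p = 0.0794) and with an intensity trend in the variance (adjusted p = 0.0592), within a range from 5.7e-07 to 0.928 over 18 alternatives.

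The list of shoot and root gravitropism genes was lower as well. Of 15 measured members, 7 fell, 1 rose and 7 did not pass, and adjusted over the list alone 8 fell and 1 rose. LZY1 led the list, followed by SGR6, a HEAT repeat gene of shoot gravitropism, which fell by 0.81 (SE 0.04), and by SGR9, a ubiquitin ligase gene of amyloplast dynamics, which fell by 0.69 (SE 0.05). LZY2 (AT1G17400) was at least 1.29-fold lower (limma adjusted p = 3.5e-04), with eal1 not well above background on any array. LZY3 was not well above background on all arrays of either genotype, and no probe was used for LZY4. Camera gave adjusted p = 0.0016, and adjusted p = 0.928 with an estimated correlation.

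Photosynthesis genes were the list with the largest upward shift. Of 38 measured members, 31 rose, 0 fell and 7 did not pass, with the same numbers adjusted over the list alone, and the median log2 ratio was 0.31. The light-harvesting genes LHCB2.2 (0.92, SE 0.04), LHCB2.1 (0.88, SE 0.05), LHCB1.1 (0.85, SE 0.04) and LHCB1.2 (0.72, SE 0.06) rose most. Their single arrays depended strongly on the dye: LHCB1.1 had log2 ratios of -0.35 and -0.44 where wild type carried Cy5 and of 2.01 and 2.16 where eal1 did. Camera gave adjusted p = 1.8e-15, and adjusted p = 0.928 with an estimated correlation. The first of these treats the members as nearly independent and takes its error across genes, not between the RNA pairs. With 1 array left out the list median lay between 0.13, without eal1-1 replicate 2, and 0.45, without eal1-1 replicate 1. It was 0.16 without eal1-2 replicate 2. With wild type given the spread of eal1, 15 members were called, all 15 of them higher.

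Cell division genes were lower. Of 32 measured members, 18 fell, 2 rose and 12 did not pass, and the median log2 ratio was -0.19. The same counts were found adjusted over the list alone. The mitotic cyclin genes CYCB2;3 (-0.37) and CYCB1;4 (-0.36) and CDC20.2 (-0.36), an activator of the anaphase-promoting complex, fell, while the A-type cyclin gene CYCA3;1 rose by 0.35 (SE 0.05). Camera gave adjusted p = 2.6e-05, and adjusted p = 0.943 with an estimated correlation. With wild type given the spread of eal1, 2 members were still called.

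**Figure D2:**
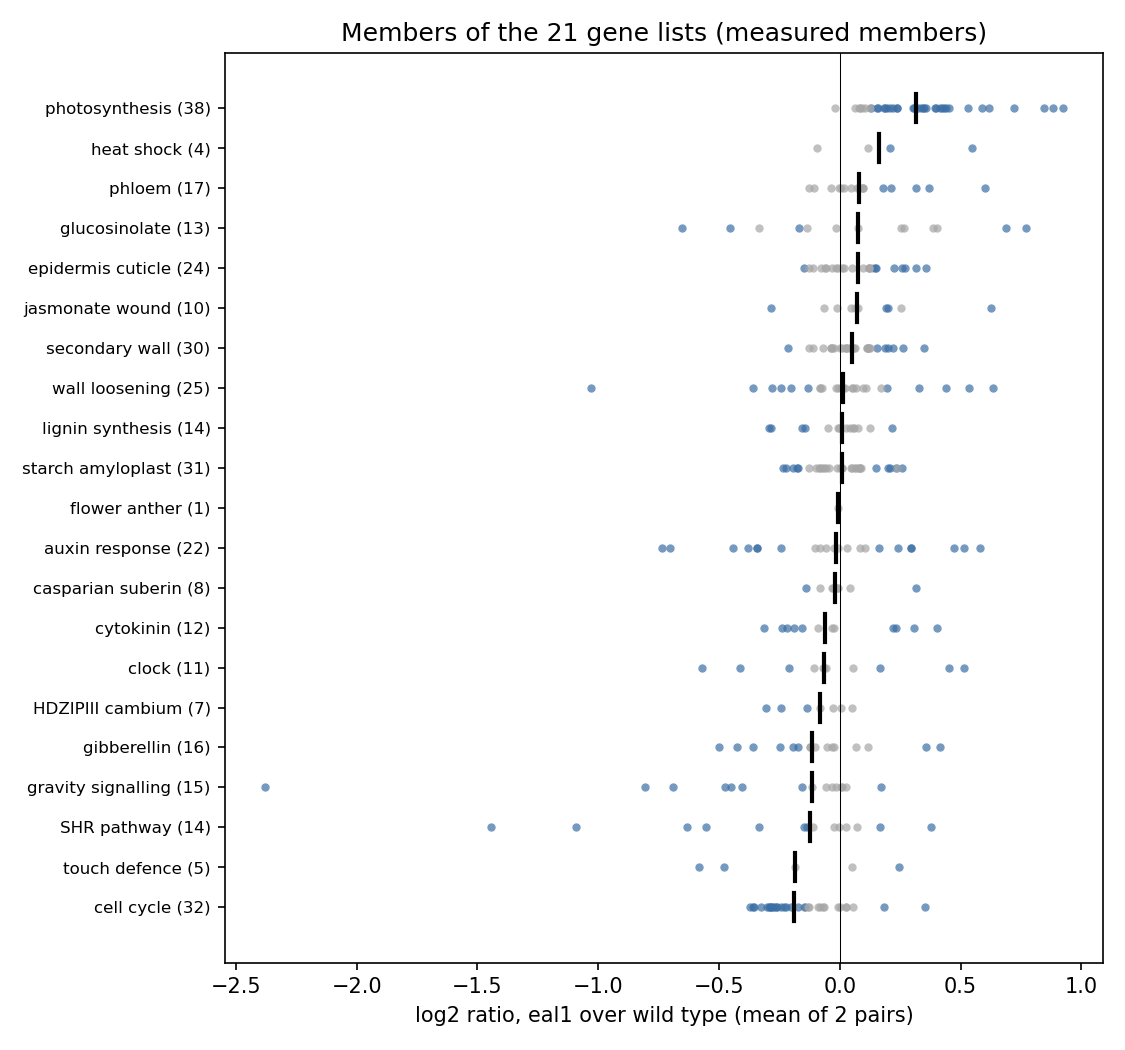
Log2 ratio of eal1 over wild type (mean of 2 pairs, horizontal axis) for each measured member of the 21 gene lists, with called members in blue, others in grey, the list median as a black bar and the number of measured members in brackets. The photosynthesis members lie to the right, with a median of 0.31, and the cell cycle members to the left, with a median of -0.19.

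The other 17 lists did not pass camera. Among early auxin response genes, 7 of 22 rose and 7 fell. GH3.3, which conjugates auxin (-0.74), and IAA17 (-0.70) fell, while SAUR15 and SAUR16 rose by 0.58 and 0.51 on the log2 scale (camera adjusted p = 0.925). Among gibberellin genes, 6 of 16 fell and 2 rose, with log2 ratios of -0.50 for GASA14, -0.43 for the biosynthesis gene GA3ox1, -0.36 for GASA1 and 0.41 for GASA6 (camera adjusted p = 0.106). Among cytokinin genes, 4 of 12 rose and 5 fell. The response regulator genes ARR6 and ARR3 rose by 0.40 and 0.31, and the cytokinin oxidase genes CKX6 (-0.32) and CKX7 (-0.24) fell (camera adjusted p = 0.854).

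Of 25 cell wall loosening genes, 5 rose and 6 fell. XTH18 fell by 1.03 (SE 0.04), while XTH22 rose by 0.63, XTH15 by 0.53 and the expansin gene EXPA8 by 0.44 (camera adjusted p = 0.925). Of 30 secondary wall genes 6 rose and 1 fell, with the fibre regulator NST1 rising by 0.35, the vessel regulator VND6 by 0.26 and TED6 by 0.22, and a log2 ratio of -0.21 for SND2 (camera adjusted p = 0.106). Of 14 monolignol synthesis genes 1 rose and 4 fell: C4H (-0.29), PAL1 (-0.28) and CYP98A3 (-0.16), the last also called C3H1, fell, and 4CL1 rose by 0.21 (camera adjusted p = 0.925). Among 7 class III HD-ZIP and cambium genes 3 fell, HB8 (-0.30), PHV (-0.25) and WOX4 (-0.14), with camera adjusted p = 0.128.

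Of 31 starch genes, 5 rose, 5 fell and 21 did not pass. SS4, which initiates starch granules, rose by 0.26 and GBSS1 by 0.23, while APL3 (-0.23) and GWD1 (-0.22) fell (camera adjusted p = 0.925). Of the 18 genes of the Casparian strip and suberin list 8 were measured. GSO1, the receptor also called SGN3, rose by 0.32 and KCS2 fell by 0.14 (camera adjusted p = 0.925). For GSO1, wild type was well above background on only 2 arrays. Of 17 phloem markers 5 rose and 0 fell, among them the sucrose transporter genes SWEET12 (0.60) and SWEET11 (0.37) and the phloem protein genes PP2A1 (0.32) and PP2A2 (0.21), with camera adjusted p = 0.0569. Of 24 epidermis and cuticle genes 7 rose and 1 fell, with CER4 rising by 0.36, CYP77A6 by 0.31, WSD1 by 0.27 and the alkane synthesis gene CER1 by 0.26 (camera adjusted p = 0.106).

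Of 11 clock genes grown under constant light 3 rose and 3 fell: PRR7 and RVE1 rose by 0.51 and 0.45, and ELF4 (-0.57) and LHY (-0.41) fell (camera adjusted p = 0.806). Of 10 jasmonate and wound genes 3 rose and 1 fell, with VSP2 rising by 0.62, JAZ8 by 0.20 and MYC2 by 0.19, and a log2 ratio of -0.28 for OPR3 (camera adjusted p = 0.269). Of 5 touch and defence genes PR5 (-0.58) and TCH3 (-0.48) fell and TCH2 rose by 0.24 (camera adjusted p = 0.275). Of 4 heat shock genes HSP70 and HSP101 rose by 0.55 and 0.21 (camera adjusted p = 0.128). Of 10 floral organ and tapetum markers only SEP3 was well above background on all arrays of a genotype, at -0.01 (limma adjusted p = 0.893).

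Among 13 glucosinolate and myrosinase genes 2 rose, 3 fell and 8 did not pass. The myrosinase genes TGG2 and TGG1 rose by 0.77 and 0.69, and CYP83B1 (-0.65) and MYB34 (-0.45), of the indole branch, fell (camera adjusted p = 0.925). The list median was 0.10 in the eal1-1 pair and -0.37 in the eal1-2 pair.

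Adjusted over the list alone, the counts changed in 6 of these lists. They were 8 higher and 7 lower for auxin, 3 and 7 for gibberellin, 10 and 2 for epidermis and cuticle, 1 and 0 for the Casparian strip and suberin, 1 and 3 for touch and defence, and 3 and 0 for heat shock. With wild type given the spread of eal1, 0 members were called in the starch, Casparian strip and suberin, monolignol, HD-ZIP and cambium, jasmonate and floral lists. That count was 8 for auxin, 5 for wall loosening, 4 for gibberellin, 3 each for clock and glucosinolate, 2 each for phloem and for touch and defence, and 1 each for cytokinin, secondary wall, epidermis and heat shock. It was 6 each for the SHR pathway and the gravitropism list. Of the genes named by list, LHCB1.1, LHCB1.2, CKX7, PP2A2, WSD1, TCH2 and SEP3 did not have the same sign on all 4 arrays.

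**Figure D3:**
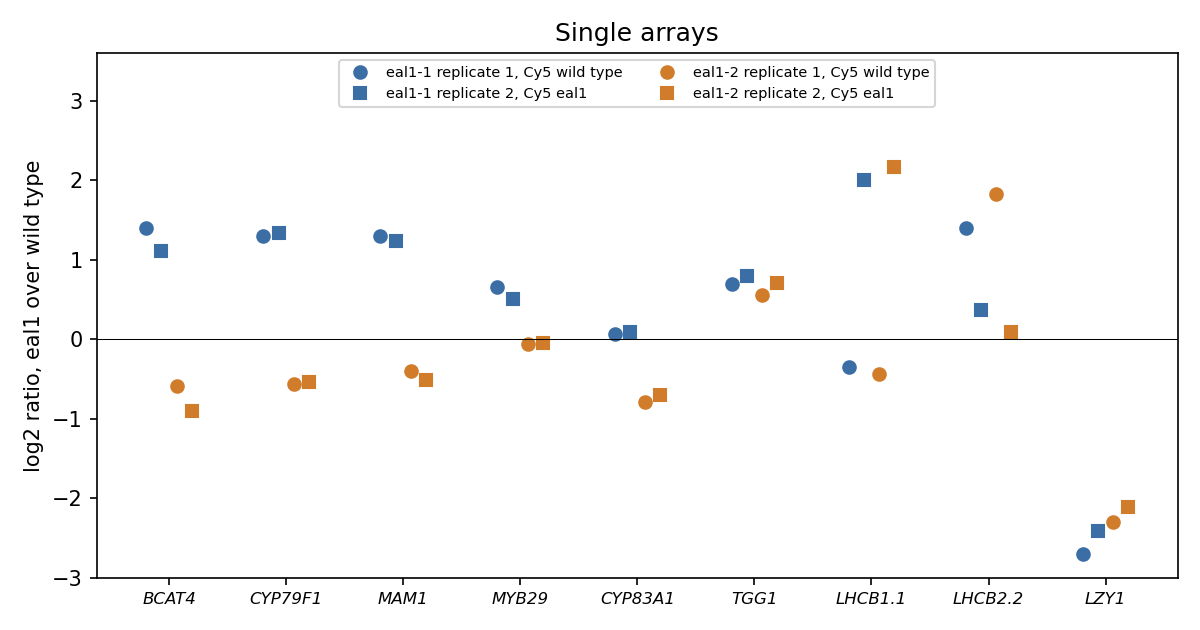
Log2 ratio of eal1 over wild type (vertical axis) on each of the 4 arrays for 9 genes, with the eal1-1 pair in blue, the eal1-2 pair in orange, arrays with Cy5 on wild type as circles and with Cy5 on eal1 as squares. BCAT4, CYP79F1 and MAM1 part by pair, LHCB1.1 and LHCB2.2 part by dye, and LZY1 lies below 0 on all 4 arrays.

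The eal1-1 and eal1-2 pairs were compared across genes, which are not independent replicates. LZY1 had log2 ratios of -2.55 in the eal1-1 pair and -2.20 in the eal1-2 pair, ADF9 of -2.58 and -2.39, and SCR of -0.67 and -0.60. Over 18374 genes Pearson's r was 0.807 and Spearman's rho 0.757, and the sign was the same for 77.4% of genes. Unchanged groups were simulated against 1 shared wild type with the spread of the eal1 RNAs. They gave r = 0.398 and 63.0% of genes with the same sign. The covariance of the pairs was 0.0272 against a simulated 0.00431. The spread of the real wild-type extract is not known, and a wider one would raise the simulated r and covariance. The simulation therefore cannot tell a genotype effect from a shared extract. Single arrays of opposite dye orientation agreed far less: r was 0.509 between the arrays of the eal1-1 pair and 0.333 between those of the eal1-2 pair, against 0.802 and 0.830 between arrays of the 2 pairs with the same orientation.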

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

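The tests of a shared wild-type extract, of the glucosinolate genes and of dye and family effects in photosynthesis genes, and the count with the spread of eal1 given to wild type, were chosen after the data had been seen.

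Several genes differed between the eal1-1 and the eal1-2 pair when single arrays were fitted in limma with a dye term. That test measures technical error only. It compares 2 eal1 RNAs, and whether they stand for 2 alleles is not given in the sources used here. Of the named genes and the glucosinolate list, BCAT4, CYP79F1 and MAM1 differed most. Among glucosinolate genes the eal1-1 pair was higher by 2.00 on the log2 scale for BCAT4, 1.86 for CYP79F1, 1.73 for MAM1, 0.82 for CYP83A1, 0.63 for MYB29, 0.47 for SUR1, 0.47 for CYP83B1 and 0.22 for CYP79B3. Among other named genes the eal1-1 pair was higher for ARD3 (0.51), VSP2 (0.38), LHY (0.29) and AT5G05250 (0.25). It was lower for AT3G01345 (-0.95), AT4G14980 (-0.48), AT2G05540 (-0.42), AT4G36850 (-0.39), TAC1 (-0.37, from fitted ratios near background), LZY1 (-0.35), CIPK20 (-0.33), GolS1 (-0.30), XTH22 (-0.29) and SHR (-0.20, adjusted p = 0.0489). In all, limma called 964 genes, 627 of them higher in the eal1-1 pair.

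Genes of the aliphatic glucosinolate branch were higher in the eal1-1 pair than in the eal1-2 pair, with log2 ratios of 1.25 and -0.75 for BCAT4, 1.31 and -0.55 for CYP79F1 and 1.27 and -0.46 for MAM1. A dye bias equal in both pairs cancels from their difference by design, so the test does not bear on it. One that differs between the pairs would give the difference opposite signs on the 2 dye orientations. That is argued against, since 83.3% of the 6 measured members had a pair difference over 0.1 on both dye orientations. A difference between wild-type extracts is argued against by a median absolute pair difference of 0.0396 in the wild-type channel and 1.25 in the eal1 channel. Genotype labels exchanged in 1 pair would turn the sign of all its ratios and are argued against by r = 0.815 between the pairs across the 18361 tested genes outside the glucosinolate list, called or not. A difference between the 2 eal1 plant pools, whether of allele, growth or segment, may lie behind it and was not tested.

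So many small calls from 2 RNA pairs were weighed against the design. Across genes, the pair difference in the wild-type channel on the Cy5 arrays had r = 0.0267 with that on the Cy3 arrays, against 0.523 in the eal1 channel, and its variance (0.00400 and 0.00646) stayed below the eal1 covariance of 0.00863, which is consistent with 1 wild-type extract in both pairs or with extracts far more alike than the eal1 RNAs. With the spread of eal1 given to wild type 770 genes were called, so that part of the 5434 calls may come from that extract. The same sign on all 4 arrays was found for 82.4% of called genes, 37.4% of tested genes and 18.4% of uncalled genes, but calling selects ratios (median 0.21) above the usual dye term (median 0.07), so the bound set for that share beforehand was wrong. A dye effect equal on both orientations cancels in the mean of each pair by design, while one that differs between orientations, and whether a given small change belongs to the genotype or to the wild-type extract, stay open.

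Photosynthesis genes were higher in eal1, with ratios that depended on the dye. The 12 members with a dye term of at most 0.25 had a median log2 ratio of 0.31, which argues against dye bias. The list median exceeded 100% of 10000 random lists matched on intensity, the highest of which had a median of 0.12, which argues against an intensity trend. The 27 members outside the LHCB1, LHCB2 and RBCS families had a median of 0.23, which argues against cross-hybridisation within these families as the whole cause. A difference between the genotypes, or a wild-type extract low in these transcripts, may lie behind the shift, and neither was tested.

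Outside the gene test, 3238 probes without a locus were well above background, and limma called 419 of them, 221 higher and 198 lower in eal1. None of these probes differed 2-fold on all 4 arrays (0 probes).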

How the results depend on the processing

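The alternative that gives wild type the spread of eal1 was chosen after seeing the data. No called list, and no named gene called in the main test, changed direction, the genes being followed over the processing, left-out array, left-out pair and wild-type spread alternatives. Uncalled SEP3, near 0, changed sign under several of them, among them the deposited ratios and without the eal1-1 pair. The main count of 5434 called genes became 3472 with normexp without an offset, 3264 with the deposited log ratios (identical in the scanner files and the series table), 953 with median centring without loess, 2517 with the 4 arrays as 4 replicates, 770 with wild type as 1 extract with the spread of eal1, and 32 when a log2 ratio of at least 1 was also asked for. With 1 array left out it lay between 2065 and 4201. With the dye orientation as a replicate block it was 7504, and 7504 is within 1.5 times the main count. That fit takes the 4 arrays as separate, so each RNA pair is counted on both dye orientations and not as 1 replicate. The replicate number marks only the dye, not a shared plant pool. The 14 genes at 2-fold on all arrays became 38 with normexp without an offset, 62 with the deposited log ratios, 6 with median centring, 85 at 1.5-fold, and 23 or 32 on the 2 arrays left without the eal1-1 or the eal1-2 pair. With 1 array left out they numbered 15 to 19. The 4 lists that camera shifted against other genes became 0 with an estimated correlation (0 of 21 with an unadjusted p under 0.05). The fry test, which asks whether a list moves from no change and not against other genes, called 0 (2 of 21 with an unadjusted p under 0.05). Camera with an estimated correlation and fry both have the 1 residual degree of freedom that 2 RNA pairs leave. They could hardly call a list, so these counts of 0 do not decide whether lists shifted. With 1 array left out 4 to 6 lists shifted. Over 18 alternatives, fry included, the adjusted p ranged from 5.7e-07 to 0.928 for the SHR pathway, from 7.5e-13 to 0.928 for gravitropism, from 1.4e-30 to 0.928 for photosynthesis and from 5.1e-07 to 0.943 for cell division. The correlation of the pairs became 0.788 with normexp without an offset, 0.712 with median centring and 0.759 without the filter, and 0.605 to 0.742 with 1 array left out, which leaves a dye effect in that pair. Of 94 named genes, 30 lost the call with median centring and 35 with the spread of wild type. The cause of these changes was not tested, except for what follows by construction. A wider error calls fewer genes, and a 2-fold count over fewer arrays cannot fall. The normexp offset shrinks the ratios of dim genes, so leaving it out can raise a 2-fold count. With 1 array left out n stayed at 2 RNA pairs, but the dye effect no longer cancelled in that pair. With the 4 arrays as 4 replicates the dye effect entered the error. Slide and scan were not run as blocks, since there was 1 of each, nor was camera with a random block. With 1 pair left no test was possible. Probes near background limit the bounds for TAC1 and LZY2. Wild type was well above background on only 2 arrays for GSO1 and JAZ8 and on 3 for SWEET11, and eal1 on 3 for GASA1.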

Other observations

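The lists below were drawn up after seeing the data, and so were all their tests. Members that had stood among the surest or largest changes were left out of the tests of the last 3 lists.

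Genes induced by low oxygen were lower in eal1. Of 23 measured genes of a core hypoxia list, 20 fell, 0 rose and 3 did not pass limma's test, and the median log2 ratio was -0.48. The log2 ratio was -1.77 for ARD3, -1.16 for FTM1, -0.94 and -0.83 for the plant cysteine oxidase genes PCO1 and PCO2, -0.77 and -0.54 for the fermentation genes PDC1 and ADH1, and -0.63 and -0.54 for the regulators HRA1 and LBD41. The ethylene response factor genes HRE1 and HRE2 had log2 ratios of 0.03 and -0.08 and did not pass. With wild type given the spread of eal1, 15 members were called. Over the measured members, 91.3% were lower in both pairs, but their values had been seen before the list was tested, so this cannot decide whether oxygen-responsive genes differ with the genotype or with the wild-type extract. Camera gave adjusted p = 1.1e-14 over the added lists, and adjusted p = 0.490 with an estimated correlation.

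Genes of salicylate-linked defence were mostly lower, and the list was drawn up because WRKY53 and LURP1 were low. Without the 3 members already seen, 7 of 12 fell and 2 rose, with a median log2 ratio of -0.24. SARD1 (-0.59), WRKY18 (-0.47), NIMIN1 (-0.47) and WRKY70 (-0.44) fell, while PBS3 and EDS5 rose by 0.18 and 0.17. Camera gave adjusted p = 0.0050 without those members, and adjusted p = 0.635 with an estimated correlation. Lower defence gene expression in eal1 is a hypothesis that this test leaves standing and that may equally reflect the wild-type extract.

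FRO1, a ferric reductase gene, rose with a log2 ratio of 0.94, and an iron deficiency response was tested as a hypothesis. Without FRO1, 3 of 6 measured members rose and 0 fell, among them OPT3 (0.41) and FRO3 (0.33), and camera gave adjusted p = 0.0630, which leaves it open. BCAT-2, a gene of branched-chain amino acid breakdown, rose with a log2 ratio of 0.94, but the other 11 genes of a sugar starvation list did not shift upward (camera adjusted p = 0.567), with 1 higher and 2 lower by limma.

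Chosen after their values were seen, the auxin efflux carrier genes PIN3 (-0.41) and PIN4 (-0.45) fell. The zinc finger gene NUC of the SHR pathway list, chosen in the same way, rose with a log2 ratio of 0.38.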
